A study of Rattus norvegicus with 4 samples.

How the data were processed

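The series compared the lateral wall of the rat cochlea after infusion of 3-nitropropionic acid (3-NP), an inhibitor of mitochondrial succinate dehydrogenase (complex II), with the same tissue after saline. Per the labels' protocols, female Sprague-Dawley rats of 180 to 210 g and 8 to 10 weeks received the solution at the round window niche of the left ear, at 300 mM for the 3-NP arrays, and the tissue was taken 1 or 3 days later. The labels describe the tissue both as the apical part of the basal turn and as the second turn without the stria vascularis. There were 4 arrays in 4 groups, with 1 array per group, so no difference has a replicate check and no p-value was computed. The number of animals behind each array is not given in the sources used here.

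Biotin-labelled cRNA was made from 6 µg of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are signal intensities per probe set on a linear scale, computed with MAS5, per the submitters' processing notes. The scaling target and detection calls are not given in the sources used here. The deposited tables show that the day 1 pair was run on a first array design, with 15923 probe sets, and the day 3 pair on another design, with 15333. These designs share 157 probe sets, of which 57 are Affymetrix controls and 100 are a common normalization set. Because day and array design coincide, day 3 was not compared with day 1 within a treatment. The comparison planned for that purpose was replaced by a comparison of the 3-NP over saline ratios between days.

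Median signals were 44.9 in saline and 60.7 in 3-NP at day 1, so the deposited values of that pair had no common median. At day 3 they were closer, at 18.7 and 20.0. Across measured genes the median log2 ratio of 3-NP over saline was 0.44 at day 1 and 0.10 at day 3. The design had assumed commonly scaled signals and took ratios as deposited as the main values. Since the day 1 shift exceeds 0.1, ratios and counts are printed relative to the median gene. Totals of genes 2-fold apart per day as deposited stand beside them, as do the as-deposited counts of several gene lists and families. Centring assumes that the median gene was equal in both arrays of a pair.

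Gene names came from the platform annotation, updated through gene identifiers to the RefSeq genes of the GRCr8 rat assembly. The array build is not given in the sources used here, so no coordinates are printed. At day 1, 12783 of 15866 probe sets outside the controls had 1 gene symbol, 312 had several and 2771 had none. At day 3 the numbers were 7564, 100 and 7612 of 15276. The single-symbol probe sets covered 10411 genes at day 1 and 5669 at day 3, of which 10378 and 5636 were named in the reference.

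Signals below an array's 30th percentile were set to that percentile, which was 17.1 and 22.0 at day 1 and 9.22 and 9.85 at day 3, for saline and 3-NP respectively. A probe set was kept when its signal reached the 50th percentile of its array in at least 1 array of the pair. Each gene was represented by its probe set with the highest mean log2 signal. A gene with 1 signal at the floor has a bound, written as an "at least" fold. Genes at least 2-fold apart, a log2 ratio of 1 or more in size, were counted as higher or lower.

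Before the data were examined, 26 gene lists were fixed, covering stress and inflammatory responses, energy metabolism and cell types that the dissection could hold. For each list with at least 5 measured genes, the median ratio was placed as a percentile among 10000 random lists of the same size, matched on signal in 10 bins. Lists outside the central 95% of the random lists are called outside the random range, as a description of these arrays. Percentiles compare genes within a pair of arrays and carry no replicate error. The rule for named genes was also fixed in advance. It took the 8 highest and 8 lowest genes per day, up to 3 bounds per direction, up to 3 members per list with a log2 ratio of at least 1 in size (otherwise the member furthest from 0), and a short panel of cochlear, succinate dehydrogenase and reference genes. The ranks and the size of 1 were taken on ratios relative to the median gene, although the design had set ratios as deposited as the main values.

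Technical spread was estimated from genes with several probe sets on an array, by comparing the brightest with the next. The SD of a single probe set's log2 ratio was 0.35 at day 1 (744 genes) and 0.47 at day 3 (803 genes). Over all these genes both probe sets lay on the same side of the median gene for 71.5% at day 1 and 66.9% at day 3. Among genes at least 2-fold apart by the brighter probe set, the other lay on the same side for 87 of 92 at day 1 and 70 of 82 at day 3. Probe sets below the filter did not enter. The 18 hybridisation spike-in probe sets had a median log2 ratio of 0.36 with an SD of 0.36 at day 1, and -0.001 with an SD of 0.15 at day 3. This spread covers probe sets and hybridisation, not animals or dissections. The number of arrays limits the precision of every value.

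The procedure was tested on simulated pairs. With a true log2 ratio of 1.5 at day 1, 96% of changed genes that passed the filter were recovered as higher, and at -1.5, 93.3% as lower. Of 6089 unchanged genes, 0.558% passed the 2-fold threshold. At day 3 the shares were 91.5%, 93.8% and 0.498% (of 3612 unchanged genes). At true ratios of 2.5 and -2.5, 100% of changed genes that passed the filter were recovered on both days. Changed genes that the filter removed do not enter these shares. At -2.5 the shares rest on 46 genes at day 1 and 42 at day 3. None of 20 simulated unchanged lists per day, drawn at random from unchanged genes, fell outside the random range. The simulated noise was a fixed setting, the same on both days, and held no differences between animals or dissections. The share of unchanged genes passing follows from that setting and is not an error rate of these arrays.

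The alternatives chosen beforehand were median centring, removal of a lowess trend with signal (span 0.4), quantile normalization, floors at the 10th and 50th percentile, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, and unmatched random lists. After the data were seen, centring on the spike-ins, centring on the 100 shared probe sets and leaving out probe sets with cross-hybridisation suffixes were added. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.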

Results

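Gene expression was measured in the cochlear lateral wall, the tissue of spiral ligament fibrocytes that recycles potassium towards the endolymph, in 1 array each from saline and 3-NP ears at day 1 and at day 3. The comparison asks how this tissue differs after acute inhibition of mitochondrial complex II, which the labels call an acute mitochondrial dysfunction model. The filter left 6533 genes at day 1 and 3974 at day 3. The 3' over 5' signal ratio of the Actb controls was 2.69 in saline and 2.53 in 3-NP at day 1, and 3.22 and 2.79 at day 3. For the Gapdh controls it was 1.34, 1.46, 1.26 and 1.17 in the same order. Bacterial poly-A control probe sets, which do not include the hybridisation spike-ins, stayed below the median signal of every array.

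At day 1 the 3-NP array had far higher signals of many, not all, interferon-induced and chemokine genes than the saline array. The medians of the immediate early and heat shock lists also lay above the range of random lists, and those of the fibrocyte, stria, and bone and cartilage lists lay below it. Cxcl10, an interferon-induced chemokine, had a signal of 48.6 in saline and 4582 in 3-NP, a 69.5-fold difference relative to the median gene. Gjb6, which encodes connexin 30, had 3139 in saline and 761 in 3-NP, with a relative log2 ratio of -2.48.

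Relative to the median gene, 507 of 6533 genes were at least 2-fold higher in 3-NP at day 1 and 423 were at least 2-fold lower. As deposited, 1169 were higher and 171 lower, so the share of higher genes among these was 87.2% as deposited and 54.5% after centring. Bounds made up 50 of the higher and 17 of the lower genes. Relative differences of at least 8-fold were seen for 39 higher and 5 lower genes (58 and 3 as deposited).

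After Cxcl10, the highest relative log2 ratios at day 1 among genes above the floor in both arrays were those of Ifit3 (5.50), Gbp2 (5.45) and Rsad2 (5.44), all interferon-induced antiviral genes. Slpi, a secreted protease inhibitor, was at 4.96, the fatty acid-binding protein gene Fabp5 at 4.80, the metalloproteinase inhibitor gene Timp1 at 4.29 and the interferon-inducible Ifi27l2b at 4.12. Among genes at the floor in saline, Ccl2, a monocyte-attracting chemokine, was at least 31.9-fold higher, Cxcl9 at least 27.8-fold and Wfdc18 at least 13.6-fold. At the other end of the genes above the floor lay the sulfotransferase gene Sult1a1 (-3.53), the lipolysis inhibitor gene G0s2 (-3.48), the aldehyde dehydrogenase gene Aldh3a1 (-3.02), Fam111a (-2.92) and the thyroid hormone transporter gene Slco1c1 (-2.88). Apbb1ip was at -2.80, the sodium leak channel gene Nalcn at -2.77 and the kinetochore gene Spc24 at -2.73. With 3-NP signals at the floor, Aass, which acts in lysine breakdown, was at least 14.1-fold lower, Tacc3 at least 8.89-fold and Cndp1 at least 5.47-fold.

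**Figure D1:**
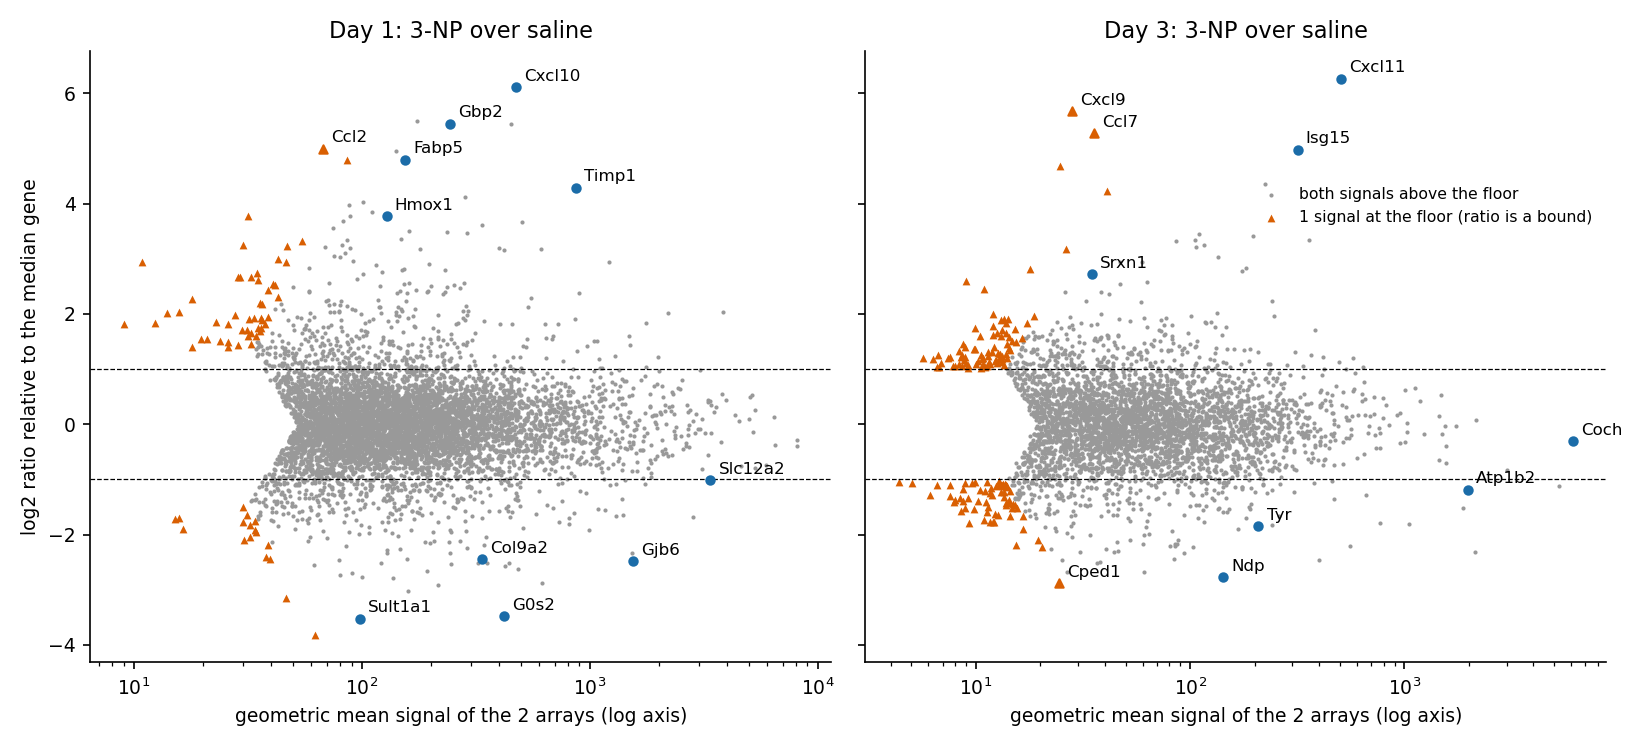
Log2 ratio of 3-NP over saline relative to the median gene (vertical axis) against the geometric mean signal of both arrays (horizontal log axis) for 6533 genes at day 1 and 3974 at day 3; dashed lines mark 2-fold and triangles mark bounds. Cxcl10 at 6.12 and Cxcl11 at 6.27 lie highest, and Gjb6 at -2.48 lies low among bright genes at day 1, while the ratio of Coch (-0.31 at day 3) turned to 0.25 under quantile normalization.

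Of 27 measured genes of antigen presentation and the interferon response, 21 were at least 2-fold higher at day 1 and 0 lower. Their median was 2.41, at percentile 100 of the random lists. The list of cytokines, chemokines and NF-kB targets had 20 of 25 genes higher and 0 lower, with a median of 1.94 at percentile 100. These 25 are the genes that passed the filter of 39 on the array. Of them 10 had 1 signal at the floor, so their ratios are bounds. Complement genes had a median of 1.01 (percentile 99.96), with C1s at 3.11, C3 at 2.76 and C1r at 1.91, and 5 of 9 genes higher. Of 15 monocyte and macrophage markers 2 were higher, Lgals3 at 2.47 and Cd14 at 1.54, and the list median was 0.44 (percentile 98.6), while 4 were higher as deposited. Only 2 neutrophil markers were measured, with a median of -0.15 that turned to 0.29 as deposited and S100a8 at -0.65, and 1 lymphocyte marker, Cd3g, at -0.98.

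Immediate early genes were higher as a group, 13 of 20 by at least 2-fold, with a median of 1.78 (percentile 100). Fos was at 3.50, the nuclear receptor gene Nr4a2 at 2.48 and Ier3 at 2.39. Dimmer probe sets of Fos and Nr4a2 were at the floor in both arrays. Heat shock genes had a median of 0.85 (percentile 100), with 5 of 13 higher (8 as deposited), led by Hspa1a at 2.81, Hspb1 at 2.29 and Hspb8 at 1.49. Of 24 antioxidant and Nrf2 target genes, 11 were higher and 4 lower (12 and 2 as deposited), with a median of 0.61 (percentile 100). Heme oxygenase, encoded by Hmox1, was at 3.77, the quinone reductase gene Nqo1 at 3.35 and mitochondrial superoxide dismutase, encoded by Sod2, at 3.16. Apoptosis and p53 target genes had a median of 0.48 (percentile 99.81), with 9 of 22 higher and 1 lower (10 and 0 as deposited). In that list the growth arrest genes Gadd45g (at least 7.64-fold higher) and Gadd45b (2.55), and the TNF receptor family gene Tnfrsf12a (2.91), stood highest.

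The list of endoplasmic reticulum stress and the integrated stress response lay inside the random range, with a median of 0.23 (percentile 94.0), 5 of 25 genes higher (8 as deposited) and 2 lower. Its members went both ways. Ppp1r15a was at 1.83 and Atf3 at least 4.52-fold higher, whereas Phgdh, the first enzyme of serine synthesis, was at -1.93. Ddit3, which encodes CHOP, was at 0.64, with signals of 148 in saline and 315 in 3-NP.

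Among energy genes, glycolysis and hypoxia genes had a median of 0.37 (percentile 99.82), with 5 of 28 higher, or 10 as deposited. Pfkfb3 was at 1.80, lactate dehydrogenase A, encoded by Ldha, at 1.51 and the phosphofructokinase gene Pfkl at 1.35. A dimmer Pfkfb3 probe set was at the floor in both arrays. The medians of 71 oxidative phosphorylation genes (-0.35, percentile 0.01) and 21 tricarboxylic acid cycle genes (-0.31, percentile 1.56) were below the random range relative to the median gene, but turned to 0.08 and 0.13 as deposited. In the former list 2 genes, and 0 as deposited, were at least 2-fold lower, Cox7a1 at -1.28 and Ndufab1 (-0.98 after lowess) with 968 in saline and 656 in 3-NP. Of the succinate dehydrogenase subunits, Sdhd was at -0.81 (-0.46 by another probe set), while Sdha (-0.34) and Sdhb (-0.35) turned to 0.10 and 0.08 as deposited. The 39 cytosolic ribosomal protein genes had a median of 0.41 (percentile 100), with Rpsa at 0.97 and 0 genes 2-fold apart, against 9 higher as deposited.

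Lateral wall genes went both ways at day 1, with list medians below the random range. Of 21 spiral ligament fibrocyte markers, 6 were at least 2-fold lower and 1 higher (4 and 3 as deposited), with a median of -0.64 (percentile 0). Of 19 ion transport and gap junction genes, 8 were lower and 3 higher (5 and 5 as deposited), with a median of -0.70 (percentile 0). Besides Gjb6, the carbonic anhydrase genes Car3 (-2.57) and Car2 (-2.05) and the potassium channel gene Kcnj16 (-1.62) were lower. Higher were the water channel gene Aqp1 (1.46) and the bicarbonate transporter genes Slc4a7 (1.22) and Slc4a4, and the connexin 43 gene Gja1 was at 0.80 and Vim at 0.79, all named after their values were seen. Slc12a2, which encodes the NKCC1 cotransporter, was at -1.01 (-0.99 after lowess), with 4109 in saline and 2761 in 3-NP, and Gjb2, which encodes connexin 26, was 1.99-fold lower relative to the median gene. Atp1b1, a sodium pump subunit, was at -0.57. A further probe set of Car3, Car2, Kcnj16 and Atp1b1 lay on the same side each time, at -3.13, -1.75, -1.10 and -0.56.

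Stria vascularis and melanocyte markers had a median of -1.35 (percentile 0), with 6 of 8 lower, but 2 as deposited, among them the endocytic receptor gene Lrp2 (-1.69) and the potassium channel subunit genes Kcne1 (-1.52) and Kcnq1 (-1.42). Of 14 bone and cartilage markers, 10 were lower (6 as deposited) and 0 higher, with a median of -1.34 (percentile 0) and values of -2.45 for Omd and -2.44 for both Col9a2 and Col11a2. Both list medians were lower together with those of the fibrocyte and ion transport lists, in tissue that one of the label fields describes as taken without the stria. Some of these lists share genes, so their medians are not separate results. Gjb6, Car2 and Slc12a2 are in the fibrocyte and ion transport lists, and Kcne1 and Kcnq1 in the ion transport and stria lists. Endothelial and mural cell markers had a median of 0.82 (percentile 99.91), with 5 of 11 higher and 1 lower, or 7 and 0 as deposited and 3 and 1 after lowess. Kdr, a VEGF receptor gene, was at 1.61, and Mcam and Plvap were at least 3.57-fold and 2.93-fold higher, but under 2-fold after lowess (0.66 and 0.87), and another Mcam probe set, below the filter, gave 0.82.

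The remaining lists at day 1 lay inside the random range or had too few genes. The median was 0.05 for 32 extracellular matrix genes (percentile 66.5), with 9 higher and 2 lower (13 and 1 as deposited). Timp1, Mmp3 (at least 6.33-fold higher) and Plau (at least 4.59-fold) led the list. A dimmer Plau probe set below the filter, at the floor in saline, gave a bound of 0.83. For 11 cell cycle genes the median was 0.19 (percentile 77.6), with 3 higher, namely Cks2 (at least 6.16-fold), Cks1b (1.29) and Pcna (1.01). A dimmer Cks1b probe set below the filter, at the floor in saline, gave a bound of 0.30. Neuron and Schwann cell markers had a median of 0.25 (percentile 93.8), with Sncg at -1.64, Prph at 1.54 and Egr2 at 1.53. A dimmer Egr2 probe set below the filter, at the floor in 3-NP, gave a bound of -0.11. Skeletal muscle markers had a median of 0.26 (percentile 80.4), with 0 higher but 2 as deposited, and Mybpc2 at 0.80. A dimmer Mybpc2 probe set below the filter, at the floor in saline, gave a bound of 0.02. For 6 organ of Corti markers the median was -0.37 (percentile 7.84) and 0.07 as deposited, and Myo6 was at -1.60. Of the erythrocyte markers 2 were measured, with a median of 0.63 and Alas2 at 0.74. Hprt1, a common reference gene, was at 0.62, and the beta-actin control probe sets lay between 0.09 and 0.29. Of 23 lists with a percentile, 11 lay above, 6 below and 6 inside the random range, against 1.15 expected outside for lists of unrelated genes. Genes of these lists can vary together and some lists share genes, so that number does not set what to expect here. The antioxidant, macrophage, endothelial and ion transport lists came inside the random range under other filters on dim genes.

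**Figure D2:**
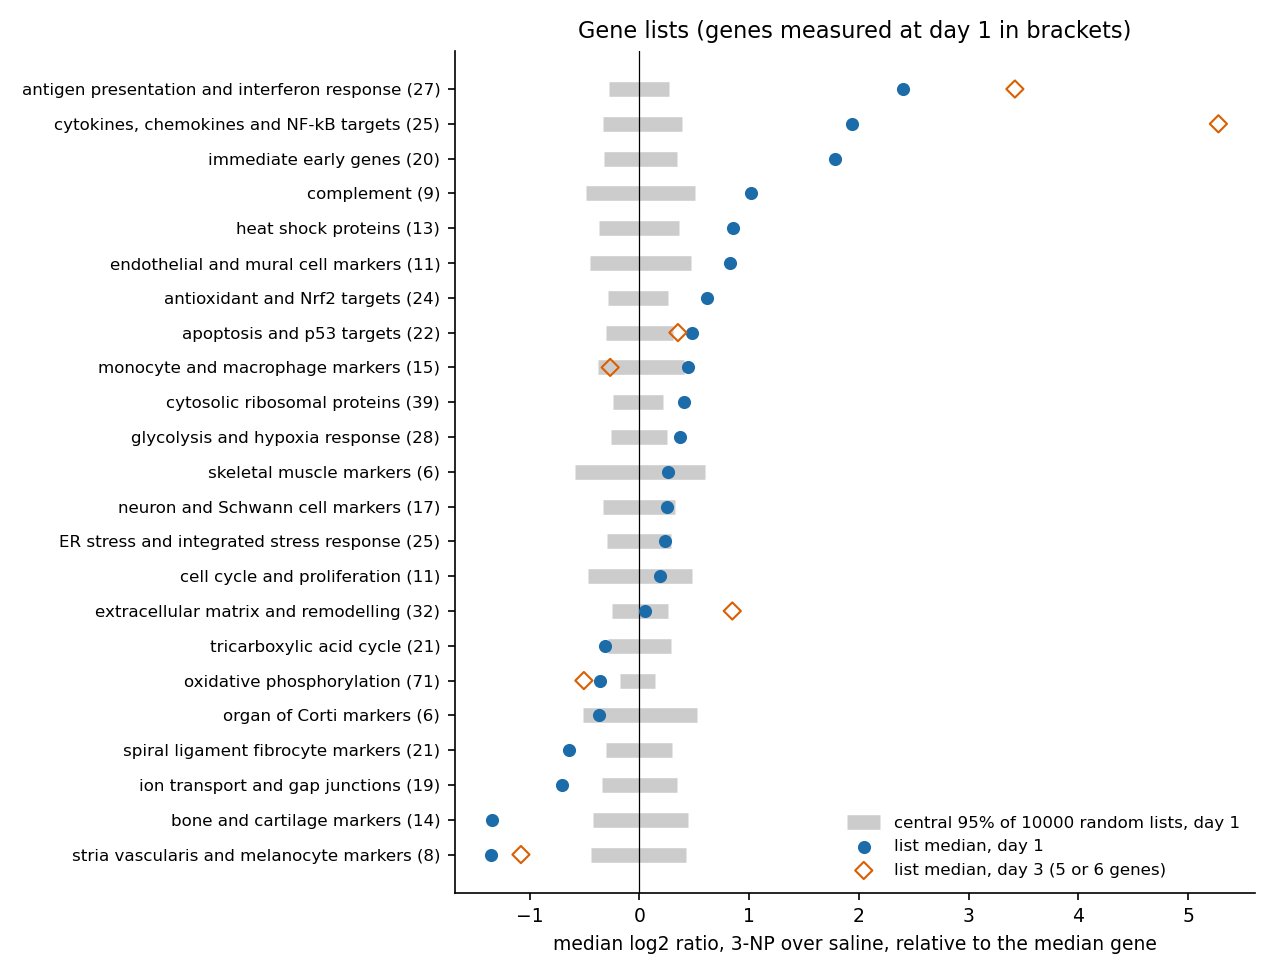
Median log2 ratio of 3-NP over saline relative to the median gene (horizontal axis) for 23 gene lists at day 1 (circles) and 7 at day 3 (diamonds); grey bars span the central 95% of 10000 random lists at day 1. The interferon list lies at 2.41 and the stria list at -1.35 at day 1, and the small negative medians of oxidative phosphorylation, tricarboxylic acid cycle and organ of Corti genes turn positive as deposited.

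At day 3, measured on the other array design, several interferon-induced and chemokine genes again had far higher signals in 3-NP, and the stria list median was lower. Cxcl11, an interferon-induced chemokine, had 55.7 in saline and 4600 in 3-NP, a 77.1-fold difference relative to the median gene. The ubiquitin-like modifier gene Isg15 was at 4.98 and Ifit2 at 4.36. Tyr, which encodes the pigment enzyme tyrosinase, had 381 in saline and 114 in 3-NP, a relative log2 ratio of -1.85.

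Relative to the median gene, 365 of 3974 genes were at least 2-fold higher at day 3 and 325 were lower, including 82 and 67 bounds. As deposited there were 432 higher and 255 lower genes, a share of higher genes of 62.9% against 52.9% after centring. Relative differences of at least 8-fold were seen for 16 higher genes and 0 lower genes.

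Further high genes at day 3 were the protease gene Adamts4 (3.46), the interferon-induced GTPase gene Igtp (3.42), Fgl2 and Cmpk2 (both 3.34) and the small GTPase gene Gem (3.32). Cxcl9 was at least 51.3-fold higher, Ccl7 at least 38.7-fold and the transcription factor gene Maff at least 25.6-fold. The lowest above the floor in both arrays were Ndp (-2.77), which encodes norrin, Msmp and Angptl1 (both -2.68), Popdc3 (-2.52), Ablim3 (-2.49), Mapk4 (-2.47), Ppp1r1a (-2.46) and Vit (-2.45). Cped1 was at least 7.38-fold lower, Mpped2 at least 4.66-fold and Wwox at least 4.59-fold. Other probe sets of Cmpk2 (3.29), Ifit2 (4.73) and Ndp (-3.76) lay close to or beyond these values. The other Igtp probe set gave 2.70, and those of Fgl2 gave 2.64, a bound with saline at the floor, and 1.24. A dimmer probe set of Wwox, below the filter and at the floor in 3-NP, gave a bound of -0.30.

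Of 5 interferon genes measured at day 3, 5 were at least 2-fold higher, with a median of 3.42 (percentile 100). Of 5 cytokine genes 3 were higher, with a median of 5.27 (percentile 100), itself the bound of Ccl7. Extracellular matrix genes had a median of 0.85 (percentile 98.4), with 1 of 5 higher, Eln (at least 2.36-fold, and 0.92 after lowess). It came inside the random range with a higher floor or no filter. Stria and melanocyte markers had a median of -1.08 (percentile 0.09), with 3 of 6 lower and 1 higher. Besides Tyr, Bsnd, which encodes the chloride channel subunit barttin, was at -1.93, and Atp1b2, a sodium pump subunit, at -1.19 (-0.78 under quantile normalization). Tyrp1 went the other way, at least 7.03-fold higher by 1 probe set and 0.69 by another. Of 5 macrophage markers 2 were lower, and 0 as deposited, Mrc1 at -1.08 and Cd163 at -1.07. A dimmer Cd163 probe set below the filter, at the floor in 3-NP, gave a bound of -0.55. The macrophage markers lay inside the random range (median -0.27, percentile 22.1). So did 5 oxidative phosphorylation genes (median -0.51, percentile 6.5), with Ndufa12 at -1.76, Atp5f1c at -1.10 and Atp5po at 1.08, and 5 apoptosis genes (median 0.35, percentile 82.3), with Fas at 1.01, 0.89 after lowess and 0.16 by a dimmer probe set below the filter.

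Other lists had fewer than 5 measured genes at day 3. The median of 4 immediate early genes was 1.49, with Nr4a3 at 1.74 and Fosl2 at least 2.38-fold higher, but under 2-fold after lowess (0.65). That of 3 heat shock genes was 1.37, with Hspa2 at 1.47 and Hsph1 at 1.37, and that of 2 antioxidant genes was 1.84, with the sulfiredoxin gene Srxn1 at 2.73 and at the floor in both arrays by a dimmer probe set. The median of 2 complement genes was 0.85, with C2 at 1.07, and of 4 endoplasmic reticulum stress genes -0.15, with Sesn2 at 1.38. A dimmer Sesn2 probe set below the filter, at the floor in saline, gave a bound of 0.30. For 3 cell cycle genes the median was 1.20, with Prc1 at 1.20 and Gmnn at least 3.90-fold higher. A dimmer Gmnn probe set was at the floor in both arrays. Of 3 fibrocyte markers with a median of -0.81, Tbx18 was at -1.19, and Coch, which encodes cochlin and had the highest 3-NP signal of that array, was at -0.31 but turned to 0.25 under quantile normalization. The median was -1.19 for 3 ion transport genes and -0.77 for 3 bone and cartilage markers, with Col11a1 at -0.96. It was 0.03 for 2 endothelial and mural markers, with Pdgfrb at 0.72 (0.36 by another probe set), 0.55 for 2 organ of Corti markers, with Sox2 at 0.84 by its brighter probe set and -0.29 by another, and -0.05 (0.05 as deposited) for 3 neuron and Schwann markers, with Pmp2 at 1.32. For 2 glycolysis and hypoxia genes it was 0.45, with Pdk4 at 0.76. The single ribosomal, neutrophil and lymphocyte genes were Rpl13a (0.48), Csf3r (-0.29) and Zap70 (0.05, which turned to -0.001 after lowess and was 0.99 by another probe set). No skeletal muscle, erythrocyte or tricarboxylic acid cycle gene passed the filter.

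The days were compared through 1246 genes measured on both designs, 1163 of them by different probe sets. Some of the genes at least 2-fold higher in 3-NP at day 1 were so at day 3 as well, 28 of 66, among them Cxcl9, the interferon-induced Parp14 (2.09 and 2.94) and Sp110 (1.26 and 1.19), the hormone gene Stc1 (2.17 and 2.94) and Srxn1 (2.39 and 2.73). Of 61 genes at least 2-fold lower at day 1, 27 were so at day 3, including Mapk4 (-2.51 and -2.47), the phosphatase inhibitor gene Ppp1r1a (-2.33 and -2.46) and the growth factor gene Fgf9 (-1.08 and -1.23). These genes, apart from Cxcl9, Srxn1, Mapk4 and Ppp1r1a, were chosen after their values were seen.

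With 97 genes at least 2-fold higher at day 3, 5.14 shared higher genes would be expected for independent lists, and with 72 lower, 3.52 shared lower genes. One gene, Sik2, was 2-fold apart in opposite directions. Across genes, which are not independent replicates, Pearson's r between days was 0.60 and Spearman's rho 0.56. Over the 100 probe sets present on both designs r was 0.69, rho was 0.68 and 80 lay on the same side of their median. The day cannot be told apart from the array design, so differences between days are not differences in time alone.

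**Figure D3:**
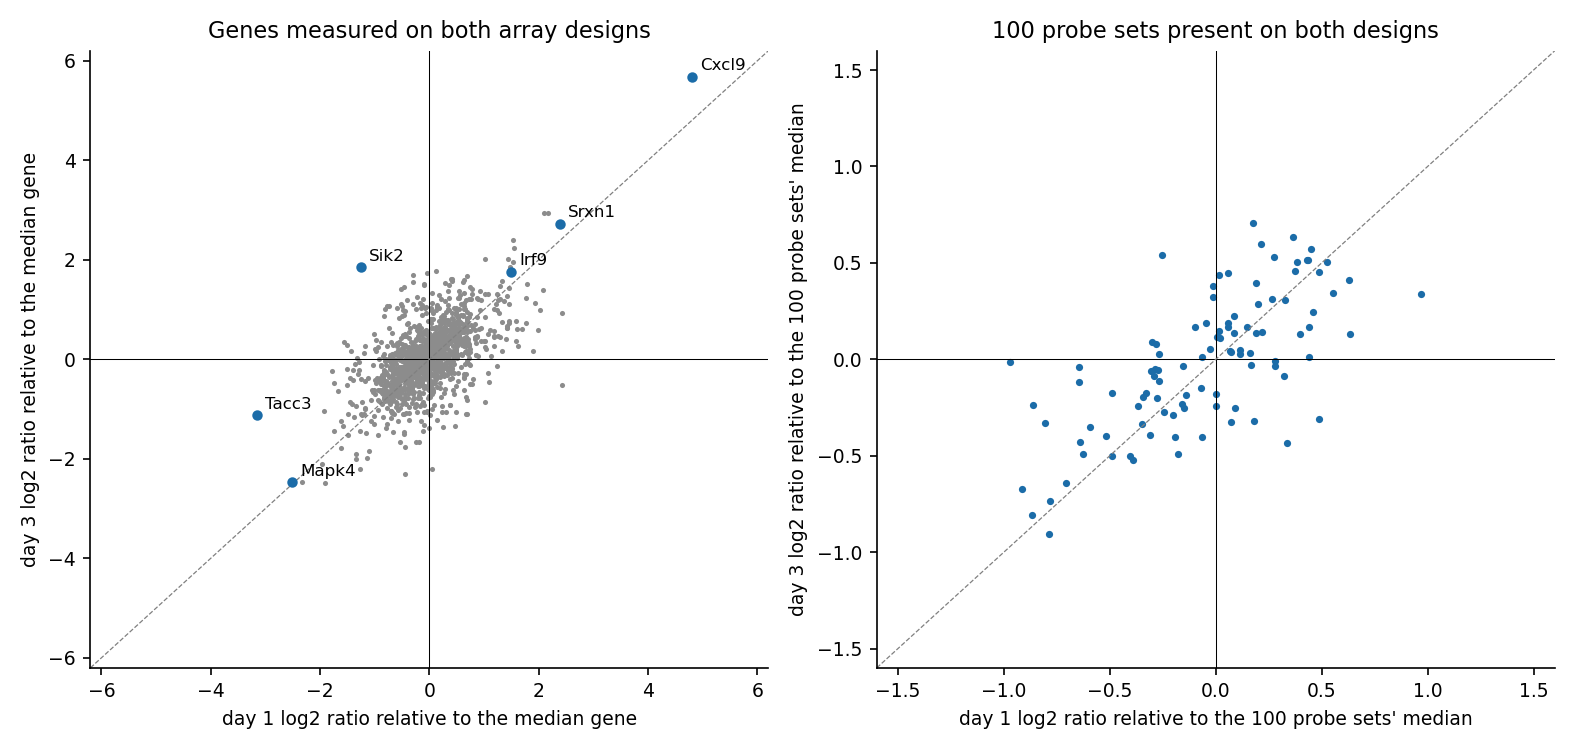
Log2 ratios of 3-NP over saline at day 3 (vertical axes) against day 1 (horizontal axes) for 1246 genes relative to the median gene and for 100 probe sets present on both designs relative to their own median; dashed lines mark equality. Genes 2-fold apart on both days lie on the same side except Sik2, at r = 0.60 over all genes, and Sik2 lies at -1.26 and 1.85.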

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

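All tests of explanations below were chosen after the results they bear on were seen. Sik2, a salt-inducible kinase gene, differed in direction between days, with a relative log2 ratio of -1.26 at day 1 (172 in saline, 97.4 in 3-NP) and 1.85 at day 3 (12.1 and 46.9), a difference of 3.11 that was not tested. Different probe sets measured it on each day, and the day 3 saline signal was near the floor. Among probe sets without a gene name, outside the gene comparisons, 63 were at least 2-fold higher in 3-NP at day 1 and 341 at day 3. The hexokinase 3' control probe set, also outside those comparisons, was at 1.11 at day 3, with 60.9 in saline and 141 in 3-NP.

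The ratios of day 1 and day 3 tracked each other, although each day had its own array design. An array-wide trend with signal is argued against, since r across genes was 0.597 after the lowess trend was removed on both days (95% bootstrap interval 0.537 to 0.654). A 3-NP effect lasting from day 1 to day 3 may account for the 55 genes at least 2-fold apart on the same side on both days. Hybridisation of the same RNA samples to both designs, for which the labels give no basis, might too: the SD of the difference between days was 1.05 times that expected from different probe sets of one gene on one array (interval 0.978 to 1.12). These 2 explanations cannot be told apart with 1 array per group.

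The medians of the interferon and cytokine lists were higher in 3-NP on both days. Scaling is argued against, as the interferon list median at day 1 was at least 2.40 under each of the 4 scalings. At day 1 the neutrophil transcripts S100a9, at 0.34 (74.6 in saline, 128 in 3-NP), and S100a8, at -0.65, were not 2-fold higher relative to the median gene. With 2 measured markers and 1 array per group, these values cannot decide whether neutrophils contributed. Neither transcript was measured at day 3. The macrophage list median at day 1 was 0.44 (0.88 as deposited), with a bootstrap interval over its genes, not over animals, of 0.19 to 0.66. That median lies between no difference and the 2-fold that an influx as the source was taken to need. A contribution of monocytes or macrophages at day 1 therefore cannot be told apart from a response of resident cells. At day 3 the list median was -0.27 over 5 markers, with 0 higher and 2 lower (0 as deposited), and this source was not tested. A 3-NP effect and a difference between animals or operations both stay open, untested.

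The medians of the stria and of the bone and cartilage lists were lower in 3-NP at day 1. Scaling is argued against, since the higher of both list medians was still -0.91 under the least favourable of the 4 scalings. The ratios of bone and cartilage members spread 2.71 times as far as probe sets of one gene, from -2.45 for Omd to 0.32 for Mepe. Those of the 8 stria members spread 1.85 times as far. Bootstrap intervals over members were 1.74 to 3.29 and 0.39 to 2.59, so only the stria interval includes 1. With 1 array per group, differences between animals would spread the members' ratios too. An equal loss of either tissue from the 3-NP dissection therefore cannot be told apart from lower expression within it. A 3-NP effect on these tissues stays open as a hypothesis.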

How the results depend on the processing

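No gene list outside the random range and no named gene 2-fold apart as deposited reversed its direction under the alternatives run, apart from the scaling flips given with their lists above. The day 1 extracellular matrix and remodelling list median, inside the range, turned to -0.25 with the 75th percentile filter. Centring on the spike-ins or on the 100 shared probe sets and leaving out cross-hybridising probe sets were chosen after seeing the data. Of 291 alternative values of 30 list results, 281 kept their side of the random range, and 23 of the lists did so under each alternative. Of 1172 alternative values of named genes, 853 moved from the ratio as deposited by less than the probe set SD and 319 by more, of which 47 with the 50th percentile floor. Median centring moved all 82 genes named at day 1 by the same 0.44, by construction. Against the printed values, relative to the median gene, only Mcam, Plvap and Fosl2 of 134 moved by more than the SD after lowess, and only Coch under quantile normalization. Against 1169 higher and 171 lower genes at day 1 as deposited, the counts were 507 and 423 after median centring, 496 and 428 after lowess and also after quantile normalization, 580 and 360 centred on the spike-ins, and 456 and 461 centred on the 100 shared probe sets, by construction of the centring. With the floor at the 50th percentile 113 were lower. With the filter at the 75th percentile, which tests fewer genes, 767 were 2-fold apart, 656 higher and 111 lower. At day 3, against 687 genes as deposited, there were 440 (286 higher, 154 lower) with the 50th percentile floor and 386 (240 and 146) with the 75th percentile filter. Without a filter the day 1 list medians were -0.076 for ion transport and 0.22 for endothelial markers, both now inside the random range, and 0.31 for neuron and Schwann markers and 0.11 for cell cycle genes, both now above it. With the 75th percentile filter the antioxidant (0.31), macrophage (0.49) and endothelial (0.58) lists came inside. The mean over probe sets put neuron and Schwann markers at 0.34, above the range. At day 3 the matrix list median was 0.22 with the 50th percentile floor and 0.057 without a filter, inside the range. Without a filter r between days was 0.47 over 2267 genes. The cause was not tested for these list and correlation changes. Planned comparisons of day 3 with day 1 within saline or 3-NP were not run, since the days used different array designs. No paired analysis was possible because each group has 1 array, and for that reason no array could be left out. Signals near the floor limit ratios to bounds, which were 67 of 930 genes 2-fold apart at day 1 and 149 of 690 at day 3.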

Other observations

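The gene families below were chosen after their values were seen. Of 13 aldehyde dehydrogenase genes, 6 were at least 2-fold lower in 3-NP at day 1 and 0 higher (3 and 1 as deposited), with a median of -0.94 that stayed negative under each of the 4 scalings. Besides Aldh3a1, the lower genes included Aldh1l1 (-1.64), Aldh7a1 (-1.49), the mitochondrial aldehyde-clearing enzyme gene Aldh2 (-1.34) and the retinoic acid-forming Aldh1a1 (-1.28). Aldh1a2, also a retinoic acid-forming enzyme gene, was at 0.81. At day 3 a different set of family members was measured, with a median of -0.12 over 5 genes, 1 of them higher and 1 lower (2 and 1 as deposited). Translation initiation factor genes, gathered by their Eif symbols, had a median of 0.42 at day 1, with 7 of 44 higher (17 as deposited), and 0.34 over 18 genes at day 3. The 44 include regulators that are not initiation factors, such as Eif4ebp1 (0.43) and the kinase gene Eif2ak2 (1.29), the latter among the 7 higher genes. Proteasome genes outside the immunoproteasome, gathered by symbol, had a median of 0.41 over 31 genes at day 1, with 0 genes 2-fold apart (7 higher as deposited). Not all of the 31 encode subunits, Psmc3ip (-0.04) being 1 that does not. At day 3 the median was 0.28 over 7 genes, with 0 higher and 1 lower. Mitochondrial ribosomal protein genes had a median of -0.08 over 69 genes at day 1 that turned to 0.36 as deposited, and 0.10 over 15 at day 3. Solute carriers as a class had a median of 0.03 over 122 genes at day 1, with 12 higher and 11 lower, or 27 and 8 as deposited.

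Class I antigen presentation genes had a median of 2.01 over 11 genes at day 1, with 9 higher, and 7 of the 11 are also in the interferon list fixed beforehand. The peptide transporter gene Tap1 was at 2.80 and the immunoproteasome subunit gene Psmb9 at 3.18. The 4 measured class II genes were at smaller values, Cd74 at 0.18, RT1-Da at 0.49, RT1-DMb at 0.50 and RT1-DMa at 0.56. At day 3 the class II gene RT1-Ba was at 1.53 and the class I gene RT1-A2 at 0.15. Among PAR bZIP and period genes of the circadian clock, Hlf was at -2.54 at day 1 (511 in saline, 119 in 3-NP), Per2 at -1.77, Dbp at -0.86 and Per1 at -0.57, and at day 3 Per3 was at -0.65 and Tef at -0.57. The 5S ribosomal RNA control probe set was at -1.18 on both days, with 410 in saline and 246 in 3-NP at day 1. Gapdh control probe sets lay between 0.44 and 0.59 on both days.

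Of the probe sets without a gene name that passed the filter, 1024 at day 1 and 3614 at day 3, a further 107 and 395 were at least 2-fold lower in 3-NP. The highest of them with both signals above the floor reached a relative log2 ratio of 3.61 at day 1 (39.7 in saline, 656 in 3-NP) and 5.53 at day 3 (10.8 and 531).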
